A study of Mus musculus with 12 samples.

How the data were processed

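Total RNA from ID8 cells was depleted of ribosomal RNA, chemically fragmented and split into an input fraction and a fraction precipitated with an antibody against ac4C, per the labels' protocols. Both fractions were made into strand-specific libraries by dUTP incorporation and read as paired ends on an Illumina instrument, per the labels' protocols. The labels give 12 samples in 4 groups of 3, control and cisplatin with input and IP each. The submitters' processing notes name fastp, FastQC, HISAT2 and HOMER and the genome build mm10, without versions or roles. The peak caller, the gene annotation used for counting and the strand setting are not given in the sources used here.

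The expression table holds FPKM values for 14852 genes in the 6 input libraries, made by the authors, with no common sum per library. It also holds the authors' log2 fold change, p-value and adjusted p-value per gene, whose test is not given in the sources used here. The peak table holds 19049 peaks with the genome coordinates deposited by the authors on mm10, which were converted to counting from 1. Coordinates given here are the outer ends of a peak, which can include introns, and the median exonic width was 181 bp. Per the file headers, each peak has the authors' fold enrichment of IP over input, the log10 of its p, a log2 difference between the treatments, and the log10 of the p and adjusted p of that difference. The deposited log10 p scores reach values far below those of a common p-value table, and the lowest log10 adjusted p, -434, is shared by 37 peaks, so peaks at it have no order. The peak table holds 1 comparison of all libraries and no value per library, and the direction of its log2 difference is not stated in the file headers. A RefSeq gene table of GRCm38.p6, the assembly behind mm10, gave gene spans; 91.0% of the gene symbols matched it, and 99.5% of those of protein-coding genes. Of 18352 peaks with a matched gene, 18030 (98.25%) overlapped the span of that gene.

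FPKM values of a gene were whole multiples of what 1 read is worth, within a tolerance of 0.0001, for 14850 of 14852 genes. The smallest whole numbers that held in all libraries were taken as the fragments per gene and library. Where the true numbers share a divisor they are understated, which can happen in genes listed at 0 in a group. The totals were 20789536, 21111362 and 19921365 for control and 23503412, 29280272 and 21437552 for cisplatin replicates 1, 2 and 3. Log2 changes from these reads differed from those in the authors' deposited table by a median of 0.00133 over 11054 genes. Intervals and limits from recovered reads cover counting error only, since the reads carry no molecular identifiers here. No pair of replicates was a repeat of a library, as the chi-square per gene of their reads was 2.32 to 3.09 within control and 7.28 to 14.18 within cisplatin libraries. Replicate numbers did not pair the samples.

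Genes with at least 1 FPKM in 3 or more input libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean trend) on log2(FPKM + 1), comparing 3 cisplatin with 3 control input libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of genes in input RNA come from this limma fit. Gene lists were tested with camera at a preset correlation of 0.01 and adjusted over 30 lists with at least 3 tested genes. Of these, 11 lists passed, 0 of them with the correlation estimated from the data. The estimate lay under the preset value for p53 targets (-0.0205), AP-1 genes (-0.0191) and TGF-beta response genes (-0.00206), and above it for the other lists that passed. A higher correlation between genes is therefore not what ended the calls of those named lists. The alternative fry, which asks whether the genes of a list move one way and does not compare them with other genes, passed 29 lists. Peaks were counted at the authors' adjusted p of 0.05, their classes compared by two-sided Fisher's exact tests, and lists tested for genes with a differential peak among the 8797 genes with a peak, 4934 of which had a differential peak (56.1%). Correlations across genes used 100000 permutations. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

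The design, the lists (28 pathway and 7 marker lists), the alternatives and the rule for named genes were fixed before the data were examined. The rule named Nat10, Thumpd1, the TGF-beta ligands and receptors and Cd274, the 10 higher and 10 lower genes with the largest log2 change whose groups do not overlap and whose higher mean is at least 5 FPKM, and up to 4 members per list with the smallest adjusted p. It left out predicted genes, pseudogenes and mitochondrial genes from the largest changes. For peaks it named the 5 higher and 5 lower with the largest log2 difference, up to 3 per list, all those in the first set of genes, and 5 genes for each combination of peak and input direction. It named 139 genes; others were chosen after their values were seen, as stated beside them, since the largest changes were mostly short RNA genes. Alternatives covered the pseudocount, the filter, 3 normalizations, each replicate left out, the replicate number as a block, other limma settings, thresholds and backgrounds. Voom on the recovered reads, leaving out genes near 0 in a group, peaks with p under 1e-10 and another background were chosen after seeing the data.

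The fit was checked on simulated data, 11449 genes with the control means and the spread of the cisplatin libraries, 200 of them changed. It recovered 52% of genes changed 1.25-fold, 68% at 1.5-fold, 78% at 2-fold and 98% at 4-fold, with 6.9% false among its calls. A list of 40 changed genes passed camera and 0 of 100 random lists did. The simulated genes varied independently, and in the list check no gene outside the planted list changed. In the data 81.3% of tested genes were called, and genes of a list can move together. The checks therefore do not give the rate of false calls under those conditions. The peak list test, run on the 8797 genes with a peak, found a list of 40 genes with planted peaks (adjusted p = 0.000104) and 0 of 100 random lists. Its simulated calls did not depend on the RNA level or the number of peaks of a gene, which real calls may do. Changes of IP RNA and of IP over input per library were planned and not run, since IP values per library were not analysed here. Base content of genes was not examined.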

Results

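The samples were ID8 cells, a mouse ovarian cancer line derived from ovarian surface epithelium, without drug (control) or treated with cisplatin, a platinum compound that crosslinks DNA. The study addressed how N4-acetylcytidine (ac4C), an acetylated base that the enzyme NAT10 places in RNA, takes part in the response to cisplatin, in the context of TGF-beta signalling and immunosuppression. Fragmented RNA from each sample was split into an input fraction and a fraction pulled down with an antibody against ac4C (IP), which gave 12 libraries in 4 groups of 3. Values per library were analysed for the 6 input libraries. The IP libraries enter through the authors' table of ac4C peaks, and their levels per library were not analysed here. The dose and the time of exposure are not given in the sources used here. The input values corresponded to 20789536, 21111362 and 19921365 fragments in listed genes for control replicates 1, 2 and 3, and to 23503412, 29280272 and 21437552 for cisplatin replicates 1, 2 and 3. Replicates of a group correlated at Pearson r of 0.989 to 0.996 over the tested genes, and control with cisplatin libraries at 0.833 to 0.847. Nothing in the labels says that replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

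The first comparison asked which RNAs differed between cisplatin-treated and control cells in the input fraction. Cells treated with cisplatin had more RNA of the p53 targets Cdkn1a, Mdm2 and Plk2, of the AP-1 genes Atf3 and Jun, and of ribosome assembly factors such as Tsr1 and Nop2. They had less RNA of replication-dependent histone genes such as Hist1h1c and of cholesterol synthesis enzymes such as Sqle. Cdkn1a, a cell cycle inhibitor, rose 27.1-fold, from 3.20 ± 0.27 to 86.8 ± 4.59 FPKM (mean ± SD, n = 3, as for all levels that follow). Hist1h1c, which encodes a linker histone, fell from 1778 ± 33.8 to 629 ± 20.8 FPKM. Nat10 itself differed little, with 6.35 ± 0.256 FPKM in control and 7.14 ± 0.319 FPKM in cisplatin libraries.

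Of 11449 genes tested with limma, 9303 (81.3%) passed an adjusted p of 0.05, 4596 of them higher and 4707 lower after cisplatin. With a fold of at least 2 in addition, 2737 genes remained, 1239 higher and 1498 lower. The median standard error of a log2 change was 0.064. The 3 cisplatin values lay wholly above or below the 3 control values in 84.2% of the tested genes, where chance gives 10%. The same held in all 147 genes of the naming rule and of the added strongest changes. Apart from the genes named outright, these were chosen by such separation or by a small p, so this is no further support. Log2 changes refer to log2(FPKM + 1) and understate the change of genes with low values. The first principal component, which separated the treatments, held 95.2% of the variance. In the authors' deposited table, 11558 genes had an adjusted p under 0.05, 5526 higher and 6032 lower, and 9076 genes were called both there and here.

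**Figure D1:**
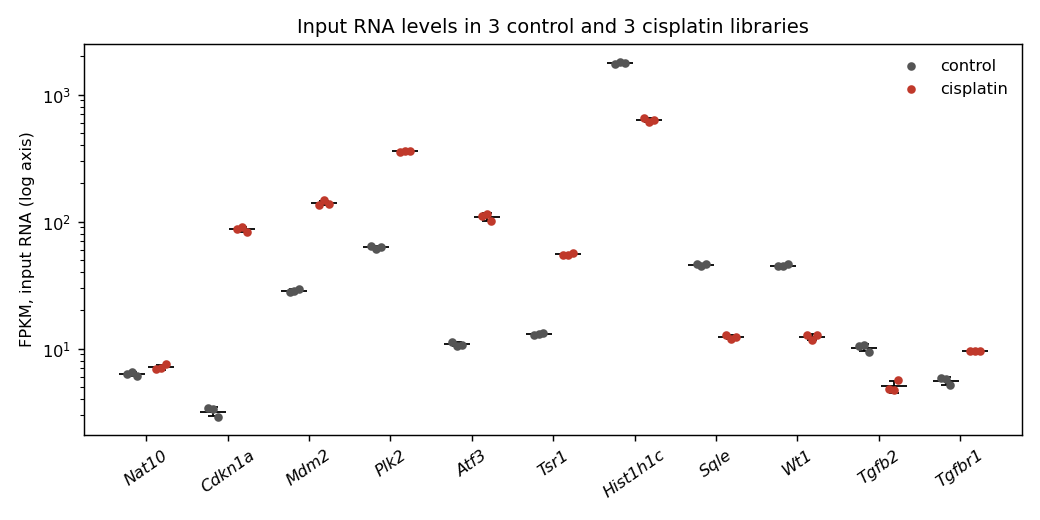
Input RNA levels of 11 named genes in FPKM on a log axis. Each point is a library, control in grey and cisplatin in red, and the black marks are the mean and SD of 3 libraries. The Cdkn1a points sit near 3.20 FPKM in control and 86.8 FPKM in cisplatin libraries, while the Nat10 points of the groups lie close together.

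Among p53 targets, 30 of 38 tested members rose and 5 fell, both over all genes tested and adjusted over the list alone. Mdm2, the ubiquitin ligase that restrains p53, went from 28.5 ± 0.768 to 140.0 ± 6.09 FPKM, the kinase gene Plk2 from 63.1 ± 1.60 to 357 ± 2.21 FPKM, and Triap1 from 6.11 ± 0.346 to 29.9 ± 0.496 FPKM. The 5 that fell, named after their values were seen, were Sesn1, Rrm2b, Tigar, Fdxr and Xpc. The list stood above other genes by camera (adjusted p = 1.21e-05, and adjusted p = 0.128 with an estimated correlation between genes). That estimate was -0.0205, so a higher correlation did not end the call. Among apoptosis genes 18 of 33 rose and 10 fell (11 adjusted over the list alone), without passing camera (adjusted p = 0.257). Pmaip1 and Bbc3, which encode BH3-only inducers of apoptosis, rose by 1.81 and 1.97 on the log2 scale, the death receptor gene Tnfrsf10b by 1.63, and Endog, a mitochondrial nuclease gene, from 0.154 ± 0.0203 to 10.8 ± 1.60 FPKM.

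Repair genes moved both ways, with 21 of 41 members of the crosslink and excision repair list higher and 14 lower, the same counts when adjusted over the list alone (camera adjusted p = 0.257). Fancd2 of the Fanconi pathway rose by 1.18 and Ercc3, a helicase subunit of TFIIH, by 1.31 on the log2 scale. Xpa, which encodes a damage recognition factor of nucleotide excision repair, went from 9.95 ± 0.804 to 0.204 ± 0.105 FPKM. A different assignment of its reads by the processing was not excluded.

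Genes of DNA replication were higher in 30 of 40 and lower in 5, also when adjusted over the list alone (camera adjusted p = 2.29e-05, and adjusted p = 0.128 with an estimated correlation). Ccne1, which encodes cyclin E, rose from 1.09 ± 0.084 to 9.85 ± 0.893 FPKM, the fork protection gene Tipin by 1.72 and the chromatin assembly gene Chaf1a by 1.13 on the log2 scale. Slbp, whose product binds histone mRNA stem loops, rose from 14.4 ± 0.161 to 35.9 ± 1.82 FPKM. Replication-dependent histone genes went the other way, with 35 of 41 lower and 1 higher (36 lower adjusted over the list alone) and a median log2 change of -1.36 (camera adjusted p = 3.54e-07, and adjusted p = 0.128 with an estimated correlation). Hist1h4c went from 25.5 ± 0.646 to 2.49 ± 0.174 FPKM, Hist1h2bj from 147 ± 5.26 to 41.4 ± 2.38 FPKM, and Hist1h2bk from 30.9 ± 1.61 to 0.932 ± 0.212 FPKM. Histone genes are near-identical copies, so the split of reads between single members is uncertain.

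In the G2/M and mitosis list, 27 of 40 genes were higher and 10 lower, also adjusted over the list alone (camera adjusted p = 0.0239, and adjusted p = 0.338 with an estimated correlation). Aurka, a mitotic kinase gene, rose by 1.43, Kif20a by 0.95 and the survivin gene Birc5 by 1.13 on the log2 scale, while Nusap1 fell by 0.74. The median log2 change of this list was 0.296. Its call was lost with quantile normalization (median 0.174, adjusted p = 0.19) and with a filter at 5 FPKM (0.296, adjusted p = 0.07). It was also lost without control replicate 1, 2 or 3 (0.292, 0.283 and 0.311, adjusted p = 0.0979, 0.101 and 0.0942). Without a control replicate the set of tested genes changed too, and the median of all tested genes moved from -0.003 to 0.081, 0.082 and 0.081.

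Ribosome biogenesis genes rose in 36 of 40 cases and fell in 2 (37 and 2 adjusted over the list alone), with a median log2 change of 0.67 (camera adjusted p = 1.39e-07, and adjusted p = 0.178 with an estimated correlation). Tsr1 went from 13.0 ± 0.24 to 55.4 ± 1.46 FPKM, Nop2 from 29.5 ± 0.487 to 92.9 ± 2.48 FPKM and Nolc1 from 64.6 ± 0.282 to 181 ± 4.74 FPKM. Cytosolic ribosomal protein genes were higher in 33 of 40 cases and lower in 1, also adjusted over the list alone, by a small median log2 change of 0.26 (camera adjusted p = 0.000241, and adjusted p = 0.338 with an estimated correlation). Rps3 and Rps9 each rose 1.42-fold, and Rpl10 was the member that fell, from 212 ± 1.35 to 167 ± 1.43 FPKM. Quantile normalization reduced the median of this list to 0.06 and ended its call (adjusted p = 0.346).

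Factors of ac4C and other RNA modifications were higher in 23 of 32 cases and lower in 5 (23 and 6 adjusted over the list alone; camera adjusted p = 0.00582, and adjusted p = 0.181 with an estimated correlation). The pseudouridine synthase gene Pus1 rose from 18.9 ± 0.368 to 54.9 ± 2.20 FPKM, the cytosine methyltransferase gene Nsun2 from 29.2 ± 0.411 to 59.6 ± 1.70 FPKM, and Trmt61a, part of a tRNA methyltransferase, from 0.178 ± 0.0616 to 3.44 ± 0.25 FPKM. Nat10 (ENSMUSG00000027185, chromosome 2, 103721258 to 103762954, mm10) measured 6.36, 6.60 and 6.09 FPKM in control replicates 1 to 3 and 6.92, 7.01 and 7.51 FPKM in cisplatin replicates 1 to 3. Its log2 change was 0.15 (SE 0.053, limma adjusted p = 0.0346), and the exact two-sided permutation test of 3 against 3 gave p = 0.1, the smallest it allows. The Nat10 call was lost when libraries were rescaled to a common sum (log2 change 0.07, adjusted p = 0.317), with voom on recovered reads, chosen after seeing the data (0.10, adjusted p = 0.124), with the replicate number as a block (adjusted p = 0.0706), and without control replicate 1 (adjusted p = 0.0797), control replicate 3 (0.113) or cisplatin replicate 3 (0.0771). Thumpd1, a tRNA-binding partner of NAT10, went from 39.3 ± 0.767 to 46.0 ± 3.80 FPKM (log2 change 0.22, adjusted p = 0.00982), a call that was lost with rescaling (0.12, adjusted p = 0.0792) and quantile normalization (0.06, adjusted p = 0.4).

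TGF-beta response genes were higher in 18 of 24 cases and lower in 4 (18 and 5 adjusted over the list alone; camera adjusted p = 0.00495, and adjusted p = 0.141 with an estimated correlation). Id1 rose from 44.9 ± 2.57 to 198 ± 18.7 FPKM, the matricellular genes Ctgf and Cyr61 by 1.74 and 1.01 on the log2 scale, and Junb by 1.42. Ligands and receptors themselves moved both ways. Tgfb2 fell from 10.2 ± 0.664 to 5.06 ± 0.551 FPKM and Tgfb3 from 43.7 ± 1.07 to 33.3 ± 0.714 FPKM. Tgfb1 was also lower, with 3.80 ± 0.296 against 2.83 ± 0.513 FPKM (adjusted p = 0.019), but lost its call with quantile normalization (adjusted p = 0.0543) and without cisplatin replicate 1 (0.0644), control replicate 2 (0.0612) or control replicate 3 (0.0628). Tgfbr1, the type I receptor gene, rose from 5.61 ± 0.408 to 9.62 ± 0.0253 FPKM. Tgfbr2 was 22.4 ± 0.364 in control and 20.2 ± 1.10 FPKM in cisplatin libraries (adjusted p = 0.0212), a call lost without cisplatin replicate 1 (adjusted p = 0.0698), control replicate 1 (0.0575) or control replicate 2 (0.0779). Inhba, the activin A subunit gene, rose from 0.119 ± 0.0223 to 2.90 ± 0.281 FPKM, and Acvr1 fell from 17.4 ± 0.193 to 5.37 ± 0.466 FPKM. The list of pathway components had 8 of 30 higher and 19 lower, the same adjusted over the list alone, and did not pass camera (adjusted p = 0.218).

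The lists of genes with immune functions did not pass camera, and single members changed in both directions. Cd274, which encodes the checkpoint ligand PD-L1, had 1 read over the 3 control libraries and 394 reads over the 3 cisplatin libraries, where its mean was 1.44 FPKM (1.55, 1.22 and 1.54). Pdcd1lg2, the gene of PD-L2, was listed at 0 in the 3 control libraries and at 2.03, 1.89 and 2.45 FPKM in cisplatin replicates 1 to 3. Ptgs2, the inducible cyclooxygenase gene, rose from 58.6 ± 0.791 to 124 ± 0.668 FPKM, and the galectin genes Lgals3 and Lgals9 rose by 1.16 and 0.92 on the log2 scale. In the list of checkpoints and immunosuppressive factors 7 of 18 were higher and 8 lower, also adjusted over the list alone (camera adjusted p = 0.783). Among chemokines and cytokines 9 of 15 were higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.257). Cxcl10 rose from 2.07 ± 0.271 to 32.0 ± 0.927 FPKM and Lif from 2.01 ± 0.0954 to 13.6 ± 0.52 FPKM, while the neutrophil chemoattractant gene Cxcl1 went from 8.22 ± 0.309 to 0.0688 ± 0.0674 FPKM. Ccl7 had 2 reads in control and 507 reads in cisplatin libraries. Cd274, Pdcd1lg2, Ccl7, and Usp18 and Areg below belong to 230 protein-coding genes with at most 3 reads in a treatment group and at least 1 FPKM in each library of the other. For these genes a different assignment of reads by the processing was not excluded. The same holds for other genes near 0 in a group, among them Xpa, Endog, Trmt61a and Inhba above, Cxcl1, and Bnip3 and Serpinb6c below.

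Interferon response genes were higher in 10 of 23 cases and lower in 7, also adjusted over the list alone, with a median log2 change of -0.004 and a mean of 0.149 (camera adjusted p = 0.783). Oasl1 rose from 9.99 ± 1.26 to 24.5 ± 2.88 FPKM, whereas Usp18 measured 1.14, 1.33 and 1.36 FPKM in control libraries and was listed at 0 in the 3 cisplatin libraries. Of MHC class I presentation genes 7 of 17 were higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.454). B2m rose from 58.3 ± 0.876 to 118 ± 4.39 FPKM and H2-D1 by 0.79 on the log2 scale, and the peptide-trimming gene Erap1 fell by 1.26. NF-kB targets had 13 of 25 higher and 9 lower, also adjusted over the list alone (camera adjusted p = 0.426), among them Ier3, which rose from 34.2 ± 0.611 to 154 ± 5.92 FPKM, and the feedback inhibitor gene Tnfaip3, which rose by 2.01 on the log2 scale. Senescence-associated secretory factors had 10 of 20 higher and 8 lower, also adjusted over the list alone (camera adjusted p = 0.426). The EGF receptor ligand gene Ereg rose from 5.93 ± 0.299 to 32.1 ± 0.453 FPKM, and Areg had 3 reads in control and 1355 reads in cisplatin libraries.

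Immediate early and AP-1 genes were higher in 19 of 27 cases and lower in 5, also adjusted over the list alone (camera adjusted p = 0.00198, and adjusted p = 0.128 with an estimated correlation). Atf3 rose from 10.8 ± 0.355 to 109 ± 7.53 FPKM, Jun from 54.7 ± 1.95 to 244 ± 9.45 FPKM and the phosphatase gene Dusp1 from 13.6 ± 0.408 to 43.7 ± 0.0639 FPKM. The 5 that fell, named after their values were seen, were Fos, Egr1, Fosb, Ier2 and Klf2. Heat shock genes were higher in 14 of 19 cases and lower in 3, also adjusted over the list alone (camera adjusted p = 0.0326, and adjusted p = 0.385 with an estimated correlation). Hsp90aa1 rose from 434 ± 2.68 to 891 ± 42.2 FPKM and Hspe1 by 1.20 on the log2 scale. The heat shock list had a median log2 change of 0.258. Its call was lost with quantile normalization (median 0.129, adjusted p = 0.19) and a filter at 5 FPKM (0.24, adjusted p = 0.0791). It was also lost without control replicate 1, 2 or 3 (0.289, 0.208 and 0.278, adjusted p = 0.0883, 0.0921 and 0.0942), where the set of tested genes changed too. Genes of the unfolded protein and integrated stress responses were higher in 8 of 32 cases and lower in 20, also adjusted over the list alone (median log2 change -0.349, camera adjusted p = 0.0981). The list passed with quantile normalization (median -0.524, adjusted p = 0.011). It also passed without control replicate 1, 2 or 3 (-0.348, -0.326 and -0.327, adjusted p = 0.0277, 0.0281 and 0.0311), where the set of tested genes changed too. Herpud1, of endoplasmic reticulum degradation, fell from 34.6 ± 0.54 to 14.7 ± 0.393 FPKM and the chaperone gene Pdia4 from 184 ± 3.23 to 100.2 ± 0.866 FPKM, while Ddit4 rose by 1.31 on the log2 scale.

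Cholesterol and fatty acid synthesis genes were lower in 27 of 32 cases and higher in 3, also adjusted over the list alone, with a median log2 change of -0.64 (camera adjusted p = 1.9e-05, and adjusted p = 0.144 with an estimated correlation). Sqle, the squalene epoxidase gene, fell from 45.9 ± 0.722 to 12.4 ± 0.485 FPKM, the squalene synthase gene Fdft1 from 50.5 ± 1.17 to 16.5 ± 0.60 FPKM and Cyp51 from 101 ± 1.28 to 42.7 ± 1.20 FPKM. The other metabolic lists did not pass camera. NRF2 and oxidative stress genes had 12 of 31 higher and 9 lower (11 and 9 adjusted over the list alone; adjusted p = 0.783), with a median log2 change of 0.06, a mean of -0.08 and an upward camera direction, and Gsta3 fell by 1.89 on the log2 scale. Glycolysis and hypoxia genes had 10 of 31 higher and 12 lower (10 and 11 adjusted over the list alone; adjusted p = 0.991), with a median of 0.03, a mean of -0.03 and an upward camera direction. Bnip3, a mitophagy receptor gene, went from 4.69 ± 0.223 to 0.231 ± 0.0623 FPKM. Nuclear oxidative phosphorylation genes had 8 of 38 higher and 12 lower (adjusted p = 0.783), and mitochondrially encoded mRNAs had 1 of 11 higher and 7 lower (adjusted p = 0.235), both with the same counts adjusted over the list alone; mt-Nd5 fell from 287 ± 4.09 to 165 ± 12.9 FPKM. Platinum transport and detoxification genes had 4 of 13 higher and 6 lower (5 and 6 adjusted over the list alone; adjusted p = 0.832), with a median of 0.04 and a mean of 0.02 but a downward camera direction. Abcg2, an efflux pump gene, rose from 6.72 ± 0.0531 to 15.8 ± 1.82 FPKM.

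Genes of cell state changed without a common direction. In the epithelial and mesenchymal list 11 of 19 were higher and 6 lower (camera adjusted p = 0.446), and among extracellular matrix genes 8 of 23 were higher and 10 lower (camera adjusted p = 0.613), both with the same counts adjusted over the list alone. Krt8, Krt18 and Vim, which encode intermediate filament proteins, rose by 0.72, 0.92 and 0.75 on the log2 scale, and Col6a1 fell from 18.7 ± 0.307 to 6.07 ± 0.725 FPKM. Markers of the ovarian surface epithelium and mesothelium had 6 of 11 higher and 5 lower, also adjusted over the list alone, with a median log2 change of 0.16, a mean of -0.19 and an upward camera direction (adjusted p = 0.991). The transcription factor gene Wt1 fell from 45.1 ± 1.08 to 12.4 ± 0.598 FPKM and Gpm6a from 63.6 ± 1.52 to 25.3 ± 0.623 FPKM, while Aldh1a1 rose from 37.3 ± 0.496 to 63.7 ± 1.97 FPKM.

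Few markers of other cell types were among the tested genes. No tested gene came from the lists of T and NK lymphocytes, B cells or erythroid cells. In the myeloid list 1 gene was tested, the lysosomal gene Cd68, which rose from 2.41 ± 0.175 to 8.89 ± 1.21 FPKM, while Fcgr3 measured 0.74, 0.629 and 0.772 FPKM in control libraries and was listed at 0 in cisplatin libraries. In the endothelial list Tek rose from 0.846 ± 0.109 to 2.64 ± 0.146 FPKM. Of stromal markers 3 were tested. Dcn fell from 12.8 ± 0.289 to 9.90 ± 0.959 FPKM, Pdgfra fell from 6.41 ± 0.273 to 2.04 ± 0.164 FPKM, and Col1a1 rose by 0.23 on the log2 scale (camera adjusted p = 0.59).

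The rule for the strongest changes took mostly short entries of microRNA and small nucleolar RNA genes that were listed at 0 in a group. Mir5124a measured 70.1, 65.5 and 71.9 FPKM in control libraries and was listed at 0 in the 3 cisplatin libraries, and Snord53 measured 35.2, 33.0 and 30.8 FPKM and was likewise listed at 0. Snord43 was listed at 0 in control libraries and at 48.8, 36.7 and 56.3 FPKM in cisplatin libraries. These entries are among 741 genes near 0 in a treatment group, of which only the protein-coding ones were examined for causes. For the short entries a different assignment of reads by the processing was not excluded. Whether their reads come from the small RNA or from a longer transcript over it was not examined. Serpinb6c, a serpin family gene, had 6 reads in control and 4780 reads in cisplatin libraries. Among protein-coding genes with at least 1 FPKM in both group means, chosen after the values were seen, Tnnt2 rose by 2.96 and the urokinase gene Plau by 2.91 on the log2 scale. Plxna4, a semaphorin receptor gene, fell from 35.5 ± 0.986 to 3.07 ± 0.134 FPKM and Trappc9 from 22.0 ± 0.644 to 1.89 ± 0.0564 FPKM.

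**Figure D2:**
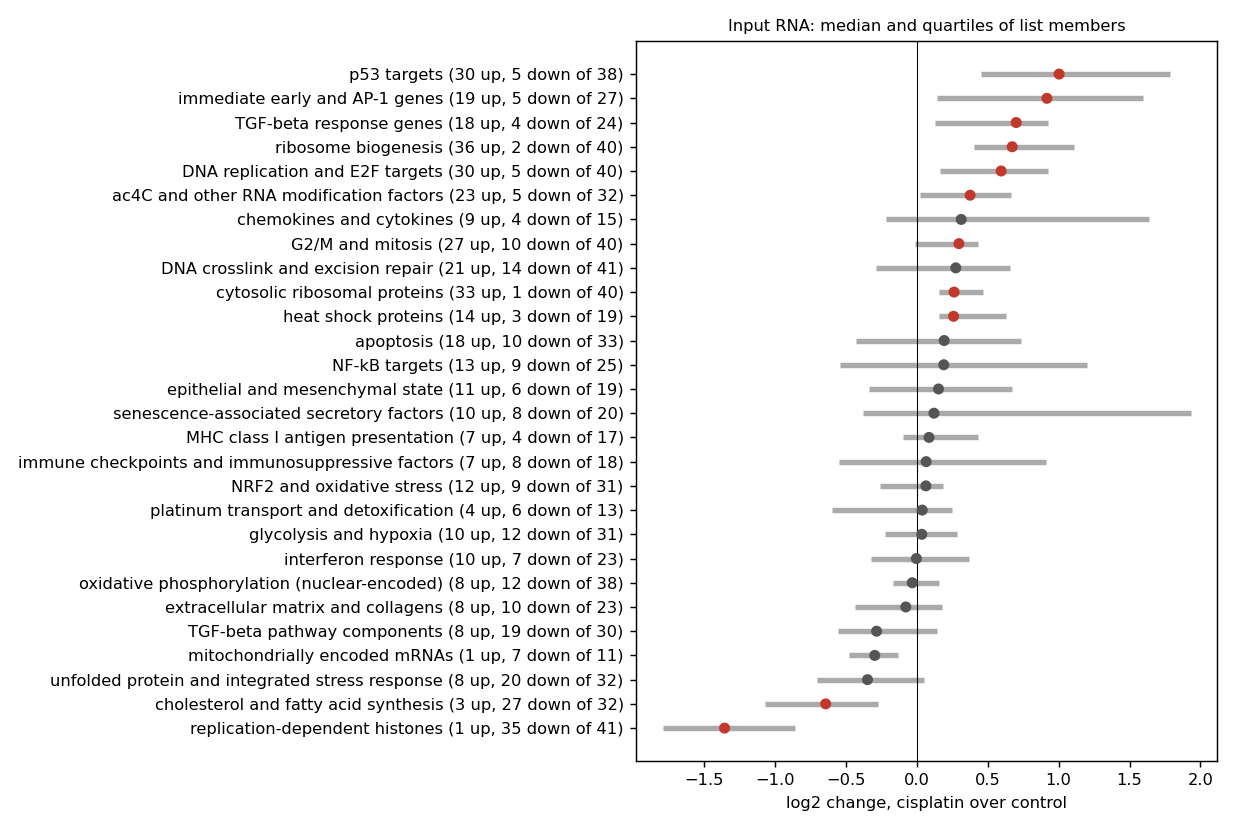
Median log2 change of input RNA, cisplatin over control, for the tested members of 28 gene lists, with bars from the lower to the upper quartile of members. Red points are the 11 lists past a camera adjusted p of 0.05, all of which lose the call with an estimated correlation, and the numbers beside each name are members higher and lower among those tested. Replication-dependent histones have the lowest median (-1.36) and p53 targets the highest (1.00).

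The second comparison asked where ac4C peaks differed between the treatments. Most peaks that differed were higher after cisplatin, if the authors' difference is read as cisplatin over control, and many of these lay in coding sequence. Positive differences also prevailed over all peaks, differential or not. All differential peaks of Mdm2, Ccng1, Mcm6, Pcna and Nop58 were higher, and those of Fth1 and Lgals1 lower. Ncl, Perp, Actb, Hsp90ab1, Scd2, Ldha, Hspa5 and Myc carried differential peaks of both directions. The authors' table gives a log2 difference for each peak without stating its direction, which is taken here as cisplatin over control from the order in which the table names the conditions. All directions of peaks rest on that reading, and with control over cisplatin each peak called higher here would be lower and the reverse.

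The authors' deposited table held 19049 peaks in 8797 genes, of which 8792 (46.2%), in 4934 genes, differed at an adjusted p of 0.05. Of these, 6959 were higher and 1833 lower, so that 79.2% were higher (lower limit of the exact 95% interval 78.3%, over peaks, which are not replicates). Under the other reading of the table, 79.2% were lower. The median log2 difference was 3.62 among higher and -2.43 among lower peaks. A higher peak was present in 4162 genes and a lower peak in 1573, with 801 genes holding both. The calls are the authors', and the spread between replicates behind them is not part of the table. Peak folds and p-values are the authors' own values for each peak.

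Coding sequence held 62.95% of higher and 54.83% of lower peaks (odds ratio 1.4, Fisher's exact adjusted p = 1.66e-09). Peaks in 3′ untranslated regions made up 22.07% of higher and 27.06% of lower peaks (odds ratio 0.764, Fisher's exact adjusted p = 2.88e-05), and peaks assigned to exons without a coding class 13.25% and 16.31% (odds ratio 0.784, Fisher's exact adjusted p = 0.0019). The share in 5′ untranslated regions was 1.67% of higher and 1.69% of lower peaks (Fisher's exact adjusted p = 0.919).

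**Figure D3:**
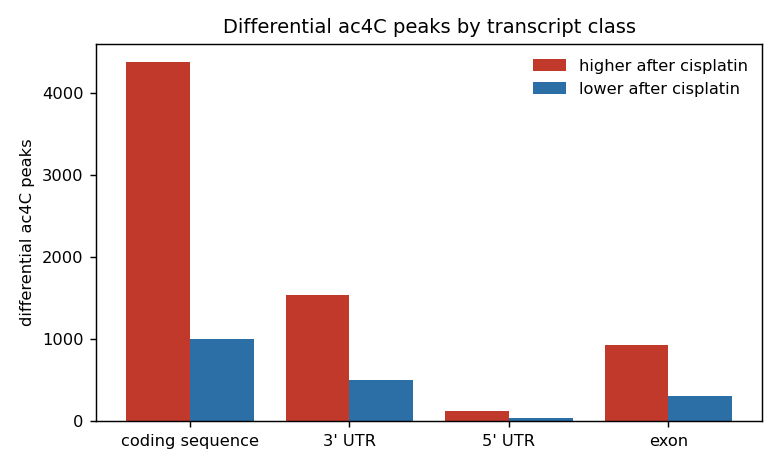
Number of differential ac4C peaks in the authors' table by transcript class, higher (red) and lower (blue) after cisplatin if the difference is cisplatin over control, with bars starting at 0. Coding sequence holds 4381 higher and 1005 lower peaks, and 3′ untranslated regions hold 1536 and 496.

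Nat10 carried 5 peaks in the authors' deposited table, all assigned to exons, and the peak at chromosome 2, 103732175 to 103733018 (mm10) was higher, with a log2 difference of 5.79 (authors' adjusted p = 5.89e-05). Thumpd1 had a higher peak in coding sequence at chromosome 7, 119716669 to 119716788 (log2 difference 5.61) and a lower peak in its 3′ untranslated region at chromosome 7, 119715777 to 119715926 (-1.56). In the TGF-beta genes the authors' deposited table gave a lower peak in the 3′ untranslated region of Tgfb2 at chromosome 1, 186624672 to 186624911 (-1.42, authors' adjusted p = 0.0214) and a higher peak in the coding sequence of Tgfb3 at chromosome 12, 86063887 to 86069425 (4.80). Tgfbr1 had lower peaks in its 3′ untranslated region at chromosome 4, 47411904 to 47412084 (-2.74) and in coding sequence at 47393456 to 47396531 (-0.78). Tgfbr2 had a higher peak in its 3′ untranslated region at chromosome 9, 116088401 to 116088641 (4.62) and lower peaks in coding sequence at 116129947 to 116131695 (authors' adjusted p = 0.00209) and 116110165 to 116129857 (-1.45). These outer ends include introns, as the exonic width was 181 bp for the last of these peaks and 121 bp for the Tgfb3 peak. The peak of Tgfb1 at chromosome 7, 25691053 to 25691202 had a log2 difference of 0.59 and an authors' adjusted p of 0.729.

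Differential peaks were found in a larger share of genes for 9 of the fixed lists than among all 8797 genes with a peak, by Fisher's exact test. The test counts any differential peak of a gene and does not account for its number of peaks or its RNA level. DNA replication genes held 117 peaks in 39 genes and ribosomal protein genes 60 in 37, against 19049 peaks in all 8797 genes. A list could pass through more peaks per gene or higher RNA levels, which was not tested. Ribosomal protein genes had a differential peak in 34 of 37 cases (adjusted p = 8.14e-05), with 33 peaks higher and 16 lower. NRF2 genes had one in 24 of 25 cases (adjusted p = 0.000249), with 34 peaks higher and 6 lower, and Pgd of the pentose phosphate pathway held a higher peak at chromosome 4, 149154205 to 149155340 (7.14), while ferritin heavy chain, Fth1, held a lower one at chromosome 19, 9982942 to 9985032 (-1.07). Genes of the unfolded protein response had one in 21 of 22 cases (adjusted p = 0.00102), with 26 peaks higher and 5 lower. Hspa5, the gene of the chaperone BiP, carried a lower peak at chromosome 2, 34775221 to 34775718 (-1.45) and a higher one. The other lists were ribosome biogenesis with 30 of 37 genes (59 peaks higher and 7 lower, adjusted p = 0.0175), DNA replication with 31 of 39 (59 and 9, 0.019), G2/M with 29 of 37 (60 and 12, 0.0267), RNA modification factors with 23 of 28 (31 and 5, 0.0267), glycolysis and hypoxia with 18 of 21 (22 and 10, 0.0267) and heat shock with 14 of 16 (25 and 5, 0.0364). With peaks limited to those whose own p is under 1e-10, a setting chosen after seeing the data, 0 lists passed, and with a fold of at least 2 in addition 3 passed.

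Single peaks of these lists differed in both directions. Mcm6, a subunit of the replicative helicase, held a higher peak in coding sequence at chromosome 1, 128343483 to 128351518 (log2 difference 2.93), and Pcna held one at chromosome 2, 132251333 to 132251542 (3.46). In nucleolin, Ncl, a coding peak at chromosome 1, 86350681 to 86351216 was higher (4.21) and another, 86357388 to 86358162, was lower. A coding peak of Mdm2 at chromosome 10, 117690220 to 117690699 was higher (3.80). The m5C methyltransferase gene Nsun2 held a higher coding peak at chromosome 13, 69621579 to 69630895 (2.47) and a lower peak in its 3′ untranslated region at 69633928 to 69634256 (-5.23). In Myc a coding peak at chromosome 15, 61989359 to 61989538 was lower (-3.48) and a peak in its 3′ untranslated region higher, while its input RNA rose by 2.19 on the log2 scale. Scd2 at chromosome 19, 44301234 to 44303359 (-2.29), Ldha at chromosome 7, 46848979 to 46851196 (-1.53) and the galectin gene Lgals1 at chromosome 15, 78926725 to 78930347 (-0.97) held lower peaks, beside higher ones in Scd2 and Ldha.

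The third comparison asked whether genes with changed peaks were those whose input RNA changed. Its directions rest on the same reading of the peak table, and under the other reading the 1752 genes below hold lower peaks with higher input RNA. Higher peaks were found together with higher input RNA in 1752 genes, among them Npm1, Hspa4 and Rpl18, where 1595 were expected among the 11449 tested genes (odds ratio 1.28, Fisher's exact p = 4.09e-10). Higher peaks with lower input RNA were found in 1420 genes, among them Aplp2 and Igf2r (odds ratio 0.708, Fisher's exact p = 1.28e-17). Lower peaks stood with higher input RNA in 622 genes, among them Actb, Hsp90ab1 and Malat1 (odds ratio 1.11, Fisher's exact p = 0.0681), and with lower input RNA in 552, among them Scd2 (odds ratio 0.844, Fisher's exact p = 0.00314). Among the 7515 tested genes that carry a peak, a background chosen after seeing the data, these odds ratios were 1.17 (Fisher's exact p = 0.000696), 0.833 (p = 0.000137), 1.00 (p = 0.953) and 0.991 (p = 0.904), so the last of the calls was lost. In this background the odds ratio of lower peaks with lower input RNA turned to 1.15 with a fold of at least 2 (Fisher's exact p = 0.0257) and to 1.22 with peak p under 1e-10 (p = 0.011), and that of lower peaks with higher input RNA to 0.775 with peak p under 1e-10 (p = 0.000545). A gene with peaks of both directions counts in both sets, as do Rpl18, Igf2r, Actb, Hsp90ab1, Malat1 and Scd2. Across these 7515 genes, which are not independent replicates, the peak difference and the input change had a Spearman rho of -0.009 (permutation p = 0.435) and a Pearson r of 0.016 (permutation p = 0.165).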

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

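Voom on recovered reads, removal of genes near 0, the 1e-10 peak limit and the background of genes with a peak were chosen after seeing the data. With a filter at 5 FPKM the genes called fell to 5934, with 2789 lower, since fewer genes were tested. With a fold of at least 2 in addition 2737 genes passed, 1239 higher and 1498 lower. Leaving out each library gave 7741 to 8666 called genes, 3712 to 4384 higher, 3382 to 4766 lower, 44.9 to 56.3% higher, and 10 to 11 gene lists. The filter stayed at 1 FPKM in 3 libraries, so genes reaching it only in the treatment of the left-out library were no longer tested. The median log2 change of all tested genes was 0.081, 0.082 and 0.081 without control replicate 1, 2 or 3. It was -0.066, -0.063 and -0.067 without cisplatin replicate 1, 2 or 3. Rescaling moved the median log2 change of all tested genes from -0.003 to -0.1. The median of a list changed sign in 5 lists with rescaling, 5 with quantile normalization, 4 with voom and 4 without each cisplatin replicate. With the other settings examined for this it changed sign in at most 2 lists. Lists past camera numbered 0 with an estimated correlation and 29 with fry. By fry's direction, NRF2 (median 0.063) and ovarian surface epithelium (0.157) reversed to downward; the cause was not tested. Nat10 lost its call with rescaling (0.067), voom (0.098), and without control replicate 1, control replicate 3 or cisplatin replicate 3 (0.116 to 0.172 over all 6); the cause was not tested. With the replicate number as a block Nat10 had the same log2 change, 0.148, and an adjusted p of 0.0706. The correlations of deviations for equal numbers were 0.097, -0.116 and 0.043, so the numbers are not read as pairs, and cisplatin replicates 1 to 3 did not each correlate best with their own number. Among named genes other than Nat10, 10 of the alternative values lost the call, in 4 genes, and 0 reversed.

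Differential peaks numbered 4934 with 1 peak per gene and 5669 with peak p under 1e-10. Lists among peaks numbered 3 with a fold of at least 2, 0 with peak p under 1e-10 and 23 against all genes of the expression table, which counts genes without any peak. The odds ratio of lower peaks with lower input RNA lost its call at 0.974 with a fold of at least 2, 0.893 with 1 peak per gene and 0.944 in coding-transcript classes. Among genes with a peak it turned to 1.15 with a fold of at least 2 and 1.22 with peak p under 1e-10, and that of lower peaks with higher input RNA to 0.775; the cause was not tested. An overlap rule for peaks without a gene was not run, as each peak had a gene, and alternatives for IP values were not run. Depth limits genes with few reads, whose folds are not given.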

Other observations

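The tests on genes near 0 in a group, on strong peaks, on the expression of long genes and on the number of genes in other splits were chosen after the result was seen; those on gene span, exonic length and the number of lists in other splits were written beforehand. Long genes fell in input RNA, with a pattern the lists do not describe. Among 10017 tested protein-coding genes, the 20% with the shortest genomic spans (median 4.6 kb) had 50.6% of genes higher and 30.9% lower after cisplatin, and the 20% with the longest spans (median 111.7 kb) had 17.9% higher and 65.4% lower. The median log2 change over these 5 groups, from short to long, was 0.18, 0.16, 0.07, -0.03 and -0.37.

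A hypothesis that longer genes lose more RNA after cisplatin was tested by Spearman's rho of log2 change with span, which was -0.255 (95% bootstrap interval -0.273 to -0.237, permutation p = 1.0e-05, the smallest the permutations can give). Genes are not independent replicates. A bias from exonic length would bring rho to near 0 once exonic length is removed from the ranks, and rho stayed at -0.213 (-0.23 to -0.193). A lower level of long genes would do so once the mean level is removed too, and rho was then -0.218 (-0.238 to -0.199). The cause of the trend stays open, since base content and RNA stability were not examined.

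Some genes had at most 3 reads in a treatment group and at least 1 FPKM in each library of the other group. They numbered 741, of which 230 were protein-coding, 116 near 0 in cisplatin and 114 in control libraries. The protein-coding ones, which include Cd274, Pdcd1lg2, Areg, Ccl7 and Usp18, had a median of 265 reads in the group that holds the gene. Against at most 3 reads in the other group, this gap is beyond counting error for the set. The limit of 1 FPKM favours genes with many reads, however. The median was therefore not free to be low and is no separate test of depth. Overlap with another RefSeq gene span, on either strand, was no more frequent among these protein-coding genes (43.5%) than among other tested protein-coding genes (46.2%, Fisher's exact p = 0.423). The annotation used for counting is not given, so overlaps in it were not tested and stay open. Reads assigned differently by the processing may still be the cause: 0 of 319 tested members of 9 families that every cell uses were near 0 where 2.67 were expected, an upper limit of 1.12 for observed over expected, which is too wide to decide, and Nme2, a widely expressed gene named after its values were seen, had 2 reads in control against 705 in cisplatin libraries. A switch in expression stays open as well.

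The strongest peaks differed from the rest, as 84 of the 182 differential peaks among the strongest 1% were lower (46.2%) against 20.3% of other differential peaks (Fisher's exact p = 1.44e-14). Among differential peaks with p under 1e-10, 78.3% were higher, so the excess of higher peaks was not confined to peaks of weak signal. Among the strongest 1%, however, 98 were higher and 84 lower. A peak's own p does not give its reads in each treatment, so few reads behind most peaks stay open as a part of the cause. For the peaks at large the difference did not follow the input change, with a rho of -0.009 over all genes and 0.029 over peaks with p under 1e-10. Whether the authors' difference is already set against input is not stated, so these values do not exclude a change of RNA level. Among the strongest 1% rho was 0.358 (95% bootstrap interval 0.208 to 0.481, 186 peaks, not independent replicates). Under the other reading of the peak difference its sign turns, and the strongest peaks move against the input RNA. A change of RNA level therefore stays open as a part of the cause there, and the sign of rho rests on the reading. A smaller share of IP reads for a few abundant transcripts stays open, since the 20.9% of lower peaks among differential peaks with p under 1e-10 outside the strongest 1%, and an interquartile range of 3.73 examined before it, do not exclude a common shift. Saturation of strong peaks, the authors' normalization of IP libraries and a change of ac4C itself stay open too.

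For the number of changed genes, 1 of 10 splits of the 6 input libraries into 3 and 3 gave as many as the real one, the real one itself, with 9303 genes against at most 0 in the others; 10 splits are too few for a share under 0.05. For gene lists, 4 of 10 splits, the real one included, gave at least the real number of 11, with up to 12 in another split. The number of lists past camera therefore does not set the real split apart from the others. Each of the other splits parts the treatments unevenly, so that lists can still move in them.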
